A study of Rattus norvegicus with 18 samples.

How the data were processed

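RNA was measured by sequencing in axoplasm, the cytoplasm squeezed out of nerve axons, taken from the proximal sciatic nerve of Sprague-Dawley rats 7 days after a crush. RNA-binding proteins were precipitated with the RNA bound to them (RIP, RNA immunoprecipitation) with antibodies to hnRNP H1, hnRNP F, hnRNP K, La/SSB or FLAG. The FLAG antibody has no target in these rats and served as the control for RNA that binds the beads or the antibody. Unprecipitated axoplasm RNA (Input) was sequenced as well. There were 3 libraries in each of the 6 groups, 18 in all, and the groups were taken from the sample titles. Nothing in the labels states that replicates came from separate animals, so the p-values measure only the spread between these libraries.

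The deposited table holds 13416 transcript entries with 12344 gene symbols, and its identifiers are Ensembl rat transcripts. 871 symbols have more than 1 entry (1928 entries together) and 15 entries have no symbol. Its counts are deposited read counts to which 1 was added, since the lowest value is 1 in 17 of the 18 libraries. In La/SSB RIP 1 every transcript has at least 10 reads (in 160 transcripts exactly 10), and no other library has such a floor. How the table was filtered is not given in the sources used here. If transcripts low in that library were removed, every comparison lacks them. The entries kept would then be partly chosen by their La/SSB level, which could favour a rise with La/SSB. The FPKM values are, per the file headers, deposited for each library; recomputed from the counts minus 1, the transcript lengths and the table's totals they deviated by at most 2.4e-14 of their size. The log2 fold changes of 9 group pairs are the authors' edgeR values, and the p_value columns hold FDR values that the authors computed with edgeR for the same pairs before deposit; both were used here for comparison only. The submitters' processing notes name CASAVA 1.8.2 and edgeR; the aligner, the read counter and the genome build are not given in the sources used here. Raw reads were not analysed here.

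Transcripts were tested one by one on the deposited counts with edgeR 4.0.16 (limma 3.58.1) in R 4.3.3. Low counts were filtered with filterByExpr by group (minimum count 10, minimum total count 15) and libraries were scaled with TMM. The quasi-likelihood F-test (glmQLFit, glmQLFTest) was two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Each RIP against FLAG RIP, hnRNP H1 against hnRNP F, and the F-test among the 4 specific RIPs used the 15 RIP libraries (13276 transcripts, 10 residual degrees of freedom). Each RIP and the FLAG RIP against Input used all 18 libraries (13300 transcripts, 12 residual degrees of freedom). Each fit shared 1 estimate of spread per transcript over all its groups, although the spread differed between groups. Calls can then be too many where a compared group varies more than the rest, and too few where both vary less. Normalised levels are TMM-scaled CPM (counts per 1e6 reads), printed as mean ± SD of 3 libraries. Log2 fold changes are printed ± SE, 3 libraries against 3. They come from the edgeR fit with its default prior count, and a prior count of 2 entered log2 CPM values only. Where all 3 libraries of a reference had 0 reads, the fold is a lower bound against 3 reads in all its libraries together; with 1 to 3 reads in the reference, the ratio of pooled read rates is given with its exact 95% counting interval. These intervals and bounds cover counting error only. Read totals per library ran from 4610750 to 16754262, so 3 reads correspond to 0.179 to 0.651 CPM.

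Chosen before the data were examined were the comparisons, the test, the gene lists, the rule for named genes and the alternatives. The 19 lists were axonally localized mRNAs, regeneration-associated genes, neuronal transcripts, the cytoskeleton of axons, cytosolic ribosomal proteins, translation factors with 5 prime TOP mRNAs (a sequence start typical of translation machinery mRNAs), nuclear-encoded oxidative phosphorylation, chaperones, hnRNP and SR protein genes, La-bound small RNAs, and transcripts of Schwann cells, fibroblasts and perineurium, macrophages and leukocytes, endothelium and mural cells, erythrocytes, skeletal muscle and adipocytes, plus mitochondrially encoded transcripts and nuclear-retained long noncoding RNAs. The last 2 had 0 members in the table and were not tested. The 17 others were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; an estimated correlation was the alternative. The La-bound small RNAs reached the test as 55 entries under 2 symbols, U6 and 7SK. Most are near-identical copies, so which copy a read came from is uncertain. The list also names Rmrp and Rpph1, the RNAs of the ribonucleases MRP and P. Their entries are named RNase_MRP and RNaseP_nuc, so they fell outside the list test. Named genes in each comparison with FLAG RIP were the 12 highest and 6 lowest log2 fold changes among called genes with a symbol, at least median abundance and no overlap between the 3 RIP and 3 FLAG libraries. In the other pairs they were 10 and 6. To these came 8 genes fixed for every comparison (Hnrnph1, Hnrnpf, Hnrnpk, Ssb, Nrn1, Hmgb1, Gap43 and Actb), up to 4 members of lowest p per list, and the 10 of lowest p among the 4 RIPs. Some genes that this rule names are not reported here. Hnrnpk and Hmgb1 were not analysed here, since no tested entry carries these symbols.

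The alternatives were DESeq2's size factors (RLE) and total counts in place of TMM, no filter, a filter of 30 reads in 3 libraries, DESeq2 1.42.0 in place of edgeR, robust moderation, only the 6 libraries compared, all 18 libraries, the replicate number as a block, each library left out in turn, and for overlaps an adjusted p under 0.1. Added after the data were seen were subtracting 1 from every count, removing each library's trend over transcript length with a lowess offset (span 0.3), counts summed per symbol, FLAG RIP 2 as the only FLAG library, the 5 other pairs of specific RIPs, 3 gene classes, leave-one-out overlaps, genes chosen without 1 library and measured in it, and the count of genes called against both references. The workflow was tested on simulated data with 200 changed transcripts. For hnRNP H1 RIP against FLAG RIP it called 40.9% of the 8-fold changes, 17.9% of the 4-fold and 0% of the 2-fold changes, with 0 unchanged transcripts called. The simulation gave each transcript the same spread in every group and changed far fewer transcripts than the real comparison called. These shares and the 0 false calls therefore do not carry over to the real comparison. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.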

Results

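Read counts per transcript were compared between RNA precipitated from regenerating rat axoplasm with 5 antibodies and the unprecipitated Input, with 3 libraries in each of the 6 groups. hnRNP H1, hnRNP F and hnRNP K are heterogeneous nuclear ribonucleoproteins, which bind RNA during its processing, transport and translation, and La/SSB binds the ends of small RNAs made by RNA polymerase III. Read totals were 4710949, 4610750 and 4731440 in the 3 Input libraries and 15476233, 7137178 and 16754262 in the FLAG RIP libraries. They were 7681993, 8882239 and 7467863 for hnRNP H1, and 6390747, 6778368 and 7267292 for hnRNP F. They were 16412065, 12682770 and 14976327 for hnRNP K, and 9768341, 8408499 and 8337028 for La/SSB. Although FLAG RIP libraries 1 and 3 were among the deepest, they had the most transcripts at 0 reads, 1601 and 1568, against 776 in FLAG RIP 2. No other library had more than 1097. The median SD of log2 CPM between replicates was also highest in the FLAG RIP, 0.98, against 0.47 in Input, 0.54 for hnRNP H1, 0.74 for hnRNP F, 0.38 for hnRNP K and 0.51 for La/SSB. Col1a1, the collagen I chain that fibroblasts secrete, took the largest share of reads in every Input and specific RIP library, from 3.74% in Input 3 to 20.42% in hnRNP K RIP 1. Fibroblast and perineurial transcripts together held 14.4%, 11.2% and 9.01% of reads in the Input libraries and up to 25.9% in hnRNP K RIP 1. Schwann cell transcripts held 0.498%, 0.562% and 0.46% of Input reads and neuronal transcripts 0.124%, 0.152% and 0.123%. In the FLAG RIP the most abundant transcript differed between libraries: the globin gene Hba1 with 2.01%, LOC100909555 with 3.89% and the apolipoprotein gene Apod with 3.28%.

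**Figure D1:**
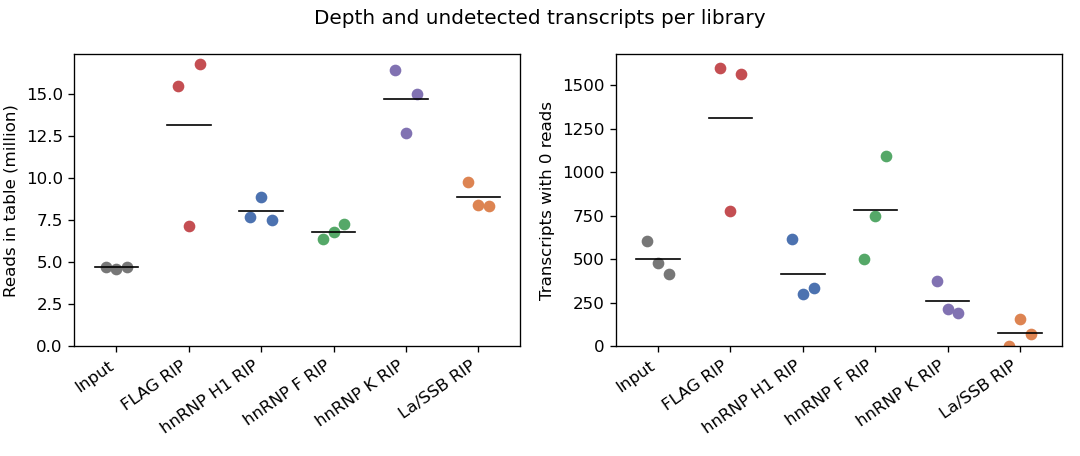
Reads in the table and transcripts with 0 reads for each of the 18 libraries, by group, with a black line at the group mean. FLAG RIP libraries 1 and 3 had 15476233 and 16754262 reads and yet 1601 and 1568 transcripts with 0 reads.

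The comparison of hnRNP H1 RIP with FLAG RIP asked which RNAs came down with hnRNP H1 beyond the background of the precipitation. Among abundant mRNAs, Bcl2l2 on chromosome 15, which codes for an anti-apoptotic protein, rose to 460 ± 29.2 CPM from 40.2 ± 14.5 CPM in the FLAG RIP (log2 fold change 3.52 ± 0.32, adjusted p = 6.37e-07). Pmp2, a lipid-binding protein of peripheral myelin, rose to 1940 ± 282 from 155 ± 41 CPM (3.65 ± 0.32). Dpysl2, a tubulin-binding protein of growing axons, rose by 2.71 ± 0.26, and Gap43, a membrane protein of growth cones, on chromosome 11, rose to 122 ± 18.5 from 16.1 ± 7.41 CPM (2.92 ± 0.42, adjusted p = 4.14e-05). Cfl1, the actin-severing protein cofilin, fell to 111 ± 12.9 from 1031 ± 268 CPM (-3.21 ± 0.35). Dcn, the matrix proteoglycan decorin, fell to 247 ± 30.8 from 2121 ± 753 CPM. The largest rises were in transcripts that the FLAG libraries barely held. Mir142, a microRNA gene of blood cells on chromosome 10, rose by 8.39 ± 0.83, and Sema3g, a secreted semaphorin, by 7.89 ± 0.88. The pooled ratio was 1673 (95% counting interval 299 to 66151) for the phosphatase inhibitor gene Ppp1r11, with 1 FLAG read. Cacna2d1, a calcium channel subunit, had 0 reads in all 3 FLAG libraries and was at least 289-fold higher. The largest falls were in Tor1aip2 (-6.22 ± 0.99), a nuclear envelope protein, and Pafah1b3 (-6.09 ± 1.00). All of these rose or fell with 3 libraries on one side of the other 3.

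By group, nuclear-encoded oxidative phosphorylation, the mitochondrial respiratory chain, fell most evenly in the hnRNP H1 RIP. Of its 69 transcripts tested, 0 rose and 58 fell (61 adjusted over the list alone). Their median log2 fold change was -2.71 (adjusted p = 1.4e-18). Atp5b, a subunit of ATP synthase, fell to 57.8 ± 6.65 from 516 ± 96.5 CPM, and Cox8a, a subunit of cytochrome oxidase, to 15.8 ± 6.77 from 271 ± 117 CPM. Of 70 cytosolic ribosomal protein transcripts 53 fell and 1 rose (56 and 2 adjusted over the list alone; median -2.22, adjusted p = 1.64e-16). Rplp0 fell by 2.38 ± 0.31. La-bound small RNAs rose in 45 of 55 entries (50 adjusted over the list alone), with a median of 4.05 and adjusted p = 1.47e-10. With an estimated correlation none of these 3 calls held. They had adjusted p = 0.16 with an estimated correlation for oxidative phosphorylation, 0.249 for ribosomal proteins and 0.145 for the small RNAs. Neuronal transcripts rose as a group (7 rose and 2 fell of 18, the same counts adjusted over the list alone; adjusted p = 0.0191, but adjusted p = 0.16 with an estimated correlation). Among them Syn1, a synaptic vesicle protein, rose by 3.24 ± 0.61. Macrophage and leukocyte transcripts fell (16 fell and 5 rose of 27, the same adjusted over the list alone; median -1.88, adjusted p = 0.00419, but adjusted p = 0.389 with an estimated correlation). Even so Gpnmb, a glycoprotein of macrophages, rose to 19409 ± 4106 from 1994 ± 747 CPM. Hba1, a globin transcript of erythrocytes, fell by 4.77 ± 0.54.

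hnRNP and SR protein genes rose in the hnRNP H1 RIP at a median of 0.72 (15 rose and 8 fell of 47, the same adjusted over the list alone). Their adjusted p was 0.0282, but 0.249 with an estimated correlation. The list names the targets of all 4 specific antibodies, of which Hnrnpk had no tested entry. Khdrbs1, the splicing regulator Sam68, rose by 3.00 ± 0.38, and Hnrnpul1 fell by 2.21 ± 0.30. That list was no longer called without FLAG RIP 2 (adjusted p = 0.0786) or when scaled by total counts (0.0524). Axonally localized mRNAs had a median of -1.29 (10 rose and 19 fell of 42, 10 and 21 adjusted over the list alone; adjusted p = 0.034, but adjusted p = 0.389 with an estimated correlation). Their call was lost without FLAG RIP 3 (adjusted p = 0.0598), hnRNP H1 RIP 1 (0.0754) or hnRNP H1 RIP 3 (0.0504), and with the length trend removed (0.0752). Translation factors with 5 prime TOP mRNAs had a median of -1.16 (6 rose and 14 fell of 31, the same adjusted over the list alone; adjusted p = 0.0178, 0.0632 with the length trend removed, and adjusted p = 0.389 with an estimated correlation). Erythrocyte transcripts had a median of -2.10 (adjusted p = 0.019, 0.0801 with the length trend removed, and adjusted p = 0.249 with an estimated correlation). Regeneration-associated genes (median 0.98, adjusted p = 0.0869), Schwann cell transcripts (0.30, 0.0869), skeletal muscle transcripts (-2.59, 0.0926) and fibroblast and perineurial transcripts (-1.03, 0.133) did not pass. Nor did endothelial and mural transcripts (-0.19, 0.735), chaperones (-0.49, 0.809), the cytoskeleton of axons (0.42, 0.889) and adipocyte transcripts (-0.28, 0.897). The test's sign differed from the median for the endothelial, cytoskeletal and adipocyte lists, and the mean of the cytoskeletal list was -0.05.

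Of the antibody targets themselves, Hnrnph1 had a log2 fold change of 0.30 ± 0.84 (adjusted p = 0.797) and Hnrnpf of 1.87 ± 1.17 (adjusted p = 0.21) in the hnRNP H1 RIP against FLAG RIP. Nrn1, the axonally transported neuritin mRNA, passed at 1.85 ± 0.65 (adjusted p = 0.0309), but not when scaled by total counts (0.0637). It did not pass either without FLAG RIP 1 (0.08), FLAG RIP 2 (0.0696), hnRNP H1 RIP 2 (0.063) or hnRNP H1 RIP 3 (0.109). In all, 5245 of 13276 transcripts were called by edgeR, 2433 higher and 2812 lower in the hnRNP H1 RIP. Scaled by total counts the split was 2015 higher and 3581 lower. That scaling moved the median of all transcripts from -0.27 to -0.61. With FLAG RIP 2 as the only FLAG library 3372 were called, and with only the 6 libraries compared 2891.

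The comparison of hnRNP F RIP with FLAG RIP asked the same of hnRNP F, a close relative of hnRNP H1. Bcl2l2 rose to 402 ± 58.8 from 40.2 ± 14.5 CPM (log2 fold change 3.32 ± 0.32, adjusted p = 1.09e-06) and Gap43 to 151 ± 55.5 from 16.1 ± 7.41 CPM (3.23 ± 0.43, adjusted p = 2.58e-05). Nefm, a neurofilament subunit of axons, rose to 335 ± 203 from 45.8 ± 26 CPM (2.87 ± 0.59). Kpnb1, importin beta, whose mRNA is translated in injured axons, rose to 2836 ± 841 from 577 ± 298 CPM. The largest rises were in AABR07051515.2, on chromosome 3 (9.18 ± 0.82), and Mir142 (8.67 ± 0.84). Tor1aip2 fell by 7.14 ± 1.05 and Cetn2, the centriole protein centrin, by 5.25 ± 0.70.

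Oxidative phosphorylation fell again with hnRNP F, in 45 of 69 transcripts with 0 higher (49 adjusted over the list alone; median -2.02, adjusted p = 8.8e-13, but adjusted p = 0.229 with an estimated correlation). Cytosolic ribosomal proteins fell in 29 of 70 (32 adjusted over the list alone; median -1.11, adjusted p = 1.35e-06, but adjusted p = 0.571 with an estimated correlation). La-bound small RNAs rose in 35 of 55 entries (38 adjusted over the list alone; median 3.28, adjusted p = 5.34e-08, but adjusted p = 0.15 with an estimated correlation). Neuronal transcripts rose in 7 of 18 with 0 lower (8 adjusted over the list alone; median 1.31, adjusted p = 0.00893, but adjusted p = 0.15 with an estimated correlation). hnRNP and SR protein genes had a median of 0.87 (17 rose and 5 fell of 47, 18 and 5 adjusted over the list alone; adjusted p = 0.0258, 0.0845 without FLAG RIP 2, and adjusted p = 0.284 with an estimated correlation). Nrn1 passed at 2.47 ± 0.67 (adjusted p = 0.00869; 0.102 with only the 6 libraries). Actb, the axonally localized beta-actin mRNA, had -0.79 ± 0.37 (adjusted p = 0.108) and Hnrnpf 0.90 ± 1.15 (adjusted p = 0.569). In all 4473 transcripts were called, 2204 higher and 2269 lower, against 1738 and 2958 when scaled by total counts. The median of all transcripts moved with it from -0.21 to -0.54. FLAG RIP 2 alone gave 2578 calls, and only the 6 libraries 1640.

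hnRNP K RIP against FLAG RIP asked the same of hnRNP K. Syt13, a synaptotagmin, rose to 39.9 ± 7.7 from 0.445 ± 0.552 CPM (6.56 ± 0.80, adjusted p = 1.61e-05). Eln, the elastic fibre protein elastin, on chromosome 12, rose to 1828 ± 774 from 39.7 ± 17.4 CPM (log2 fold change 5.53 ± 0.45, adjusted p = 3.14e-07). Cdh5, the cadherin of endothelial junctions, rose to 569 ± 159 from 35.3 ± 10.9 CPM (4.01 ± 0.37), and Bgn, the proteoglycan biglycan, to 14135 ± 4250 from 1854 ± 422 CPM (2.93 ± 0.28). Schwann cell transcripts rose in 19 of 31 with 0 lower (21 and 1 adjusted over the list alone; median 1.65, adjusted p = 2.47e-06), and this call held with an estimated correlation (adjusted p = 0.0031). Among them Ngfr, the neurotrophin receptor of injured-nerve Schwann cells, rose by 2.64 ± 0.52. Of the fixed axonal mRNAs, Nrn1 rose to 31.6 ± 5.67 from 4.87 ± 3.14 CPM (2.69 ± 0.67, adjusted p = 0.00522) and Gap43 to 58.6 ± 12.3 from 16.1 ± 7.41 CPM (1.86 ± 0.41, adjusted p = 0.0021), while Actb had 0.16 ± 0.37 (adjusted p = 0.765).

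hnRNP and SR protein genes fell with hnRNP K in 25 of 47 and rose in 2 (25 and 5 adjusted over the list alone; median -1.70, adjusted p = 4.81e-05, but adjusted p = 0.056 with an estimated correlation). Srsf5, a splicing factor, fell to 36.3 ± 2.15 from 372 ± 140 CPM (-3.36 ± 0.36, adjusted p = 4.74e-06), and Hnrnpa2b1, which carries mRNAs along axons, fell by 3.83 ± 0.49. Ssb, the La gene, fell to 13.9 ± 2.67 from 83 ± 25.2 CPM (-2.58 ± 0.41). Oxidative phosphorylation fell in 59 of 69 and rose in 1 (64 and 1 adjusted over the list alone; median -2.88, adjusted p = 6.59e-20, but adjusted p = 0.0717 with an estimated correlation). Uqcrc1, a core subunit of complex III, fell by 5.06 ± 0.64. Ribosomal proteins fell in 39 of 70 and rose in 1 (45 and 1 adjusted over the list alone; median -1.77, adjusted p = 3.53e-11, but adjusted p = 0.323 with an estimated correlation). The 1 that rose was Rpl29 (3.34 ± 0.43). Chaperones fell in 12 of 25 and rose in 4 (14 and 4 adjusted over the list alone; median -1.57, adjusted p = 0.00837, but adjusted p = 0.234 with an estimated correlation). Translation factors with 5 prime TOP mRNAs had a median of -0.91 (4 rose and 11 fell of 31, the same adjusted over the list alone). Their adjusted p was 0.0108, 0.0958 with the length trend removed, and adjusted p = 0.418 with an estimated correlation. Jun, the injury-induced transcription factor, fell by 2.71 ± 0.28. Jun was itself higher in the FLAG RIP than in Input (1.93 ± 0.26). So were Uqcrc1 (3.41 ± 0.56), Hnrnpa2b1 (2.31 ± 0.44) and Srsf5 (1.48 ± 0.31), which adds to their falls against FLAG.

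Fibroblast and perineurial transcripts rose with hnRNP K in 10 of 28 and fell in 3 (10 and 5 adjusted over the list alone; median 0.57, adjusted p = 0.000348, but adjusted p = 0.307 with an estimated correlation). Col1a1 led them, at 204113 ± 92984 against 12035 ± 4086 CPM (4.08 ± 0.37). La-bound small RNAs rose in 17 of 55 (13 adjusted over the list alone; median 1.35, adjusted p = 0.00101, but adjusted p = 0.262 with an estimated correlation). Neuronal transcripts rose in 7 of 18 with 1 lower (the same adjusted over the list alone; median 0.96, adjusted p = 0.0138, but adjusted p = 0.12 with an estimated correlation). Endothelial and mural transcripts rose in 5 of 17 (5 adjusted over the list alone; median 0.21, adjusted p = 0.0153, 0.0575 without FLAG RIP 3, and adjusted p = 0.0941 with an estimated correlation). Hnrnph1 passed at -2.77 ± 0.90 (adjusted p = 0.0242), but had -0.43 (adjusted p = 0.79) with FLAG RIP 2 alone. Its adjusted p was 0.141 without FLAG RIP 1, 0.104 without hnRNP K RIP 1 and 0.0699 without hnRNP K RIP 3. In all 4497 transcripts were called, 1921 higher and 2576 lower, against 1241 and 3680 when scaled by total counts. The median of all transcripts then stood at -0.80 in place of -0.30. Without hnRNP K RIP 1 the count was 2902, with FLAG RIP 2 alone 2672 and with only the 6 libraries 2751.

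La/SSB RIP against FLAG RIP asked the same of La/SSB. LOC100363112 had the largest rise among its named genes (7.94 ± 0.75, adjusted p = 1.25e-05). La-bound small RNAs rose in 43 of 55 entries with 0 lower (49 adjusted over the list alone). Their median was 4.59, or 4.60 with entries at 0 reads set to their bounds, and adjusted p = 4.69e-20, which held with an estimated correlation (adjusted p = 0.029). If the table was filtered on La/SSB RIP 1, that choice could add to this rise. The 7SK entry on chromosome 3, a copy of the RNA that restrains transcription elongation, rose to 17.5 ± 0.657 from 0.336 ± 0.308 CPM (log2 fold change 5.73 ± 0.82, adjusted p = 0.000428). Epb41l2, a membrane-skeleton protein, on chromosome 1, rose to 114 ± 29.7 from 0.545 ± 0.125 CPM (7.69 ± 0.59, adjusted p = 7.62e-07), and Col1a1 rose by 1.60 ± 0.33. Pabpc1, the poly(A)-binding protein, rose by 1.78 ± 0.27 and Eef1a1, an elongation factor, by 1.36 ± 0.28, while their list, translation factors with 5 prime TOP mRNAs, did not pass (median 0.06, adjusted p = 0.473). The actin regulators Pfn1, Rhoa and Cfl1 fell by 3.08 ± 0.36, 1.66 ± 0.25 and 1.61 ± 0.33. Pfn1 and Cfl1 stood higher in the FLAG RIP than in Input (1.98 ± 0.34 and 1.27 ± 0.31), which adds to their falls. In La/SSB RIP against Input, Pfn1 had -1.07 ± 0.33 (adjusted p = 0.317) and Rhoa -0.86 ± 0.23 (adjusted p = 0.232), neither called.

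Oxidative phosphorylation fell with La/SSB in 20 of 69 with 0 higher (24 adjusted over the list alone; median -1.58, adjusted p = 6.42e-12, but adjusted p = 0.171 with an estimated correlation). hnRNP and SR protein genes fell in 13 of 47 with 0 higher (14 adjusted over the list alone; median -0.72, adjusted p = 0.00202, but adjusted p = 0.123 with an estimated correlation). Ribosomal proteins did not pass, at a median of -0.08 (1 rose and 2 fell of 70, 0 and 0 adjusted over the list alone; adjusted p = 0.645). Schwann cell transcripts had a median of 0.58 (7 rose and 2 fell of 31, the same adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.0948 with an estimated correlation). Their call was lost without FLAG RIP 2 (0.0682), FLAG RIP 3 (0.0552) or La/SSB RIP 2 (0.0935). Ssb itself had -0.07 ± 0.39 (adjusted p = 0.922), and Nrn1 did not pass (adjusted p = 0.198). Gap43 passed at 1.90 ± 0.41 (adjusted p = 0.00543; 0.0561 with only the 6 libraries). In all 2492 transcripts were called, 1208 higher and 1284 lower, against 1462 and 471 when scaled by total counts, and 1126 and 709 with 1 subtracted from every count. Total counts moved the median of all transcripts from -0.32 to 0.07, and subtracting 1 moved it to -0.11. The count depended on single libraries more than in the other RIPs: it was 349 with FLAG RIP 2 alone, 674 with only the 6 libraries, 1239 without La/SSB RIP 1, 1583 without La/SSB RIP 3 and 3898 without FLAG RIP 2.

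**Figure D2:**
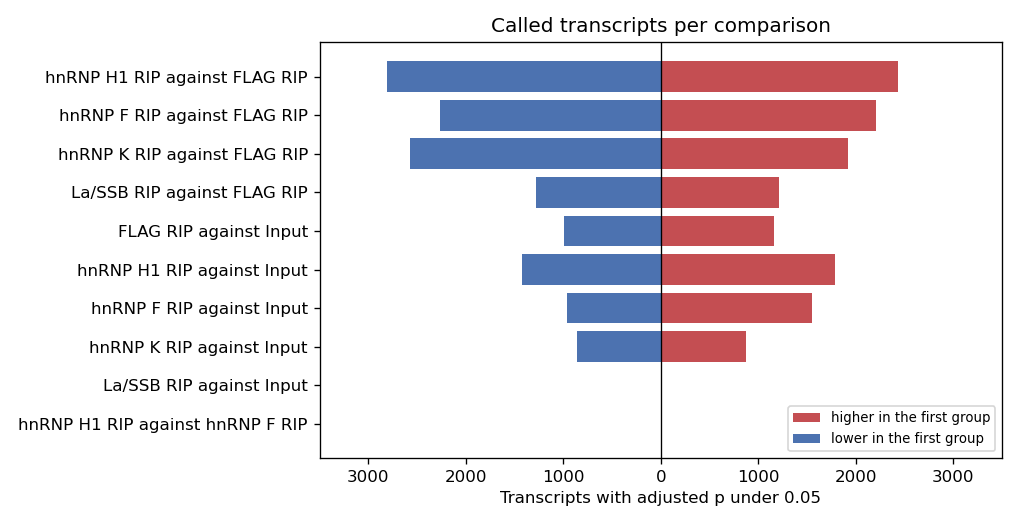
Transcripts called higher (bars to the right) and lower (bars to the left) by edgeR in each of the 10 comparisons of 2 groups. hnRNP H1 against hnRNP F has 0 calls and La/SSB against Input 5; with total counts in place of TMM the split of the La/SSB RIP against FLAG RIP turns from 1208 higher and 1284 lower to 1462 and 471.

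**Figure D3:**
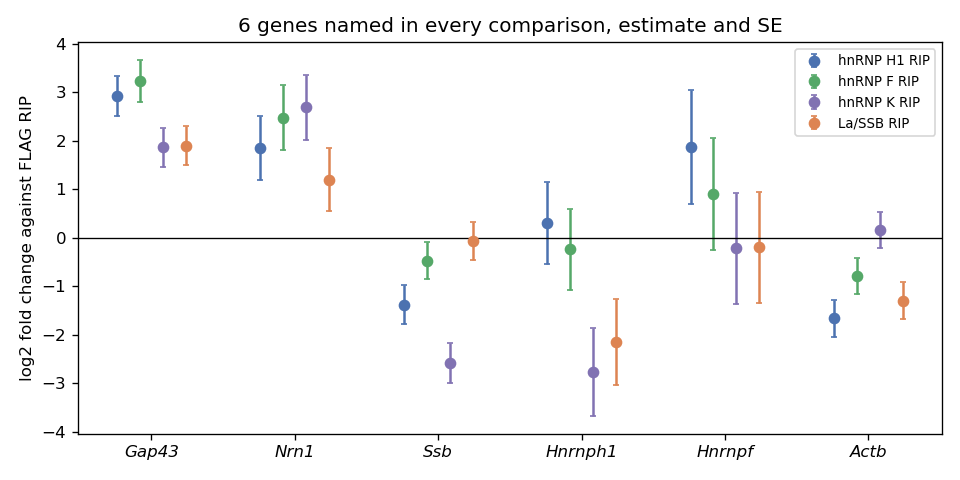
Log2 fold change ± SE against FLAG RIP (3 libraries against 3) of 6 genes fixed beforehand, in the 4 specific RIPs. Gap43 lies between 1.86 and 3.23 in all 4, and Ssb lies at -2.58 with hnRNP K and -0.07 with La/SSB. Gap43 and Nrn1 were themselves lower in the FLAG RIP than in Input (-1.85 and -1.89), which raises their values against FLAG. No sign of a called value turns with total counts.

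The overlap of the 4 sets of genes higher than FLAG asked whether the proteins bound shared RNAs. hnRNP H1 and hnRNP F shared most: 1853 genes were higher than FLAG in both, against 404 if the sets were independent, 1808 were lower in both, and 0 were called in opposite directions. hnRNP H1 and hnRNP K shared 1020 higher genes (352 if independent) and had 332 in opposite directions. hnRNP F and hnRNP K shared 931 (319 if independent), with 318 opposite. La/SSB shared 956 higher genes with hnRNP H1, 816 with hnRNP F and 809 with hnRNP K, against 221, 201 and 175 if independent. Bcl2l2, Gap43, Col1a1, Ppp1r11 and Mir142 were among the genes higher than FLAG with hnRNP H1 and hnRNP F alike. 549 genes were higher and 450 lower in all 4 RIPs, while 701 were called higher with hnRNP K and with none of the other 3, 304 with hnRNP H1, 224 with hnRNP F and 76 with La/SSB.

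All 4 comparisons used the same 3 FLAG libraries, which alone ties their fold changes together. In groups simulated without differences against shared controls, 0 genes were called in both members of a pair, with a mean correlation of 0.49 to 0.5 and a covariance of 0.34 to 0.35 across genes. All simulated groups had the same mean and spread per gene, whereas the real FLAG libraries varied most (median SD 0.98). The simulated values therefore do not bound what the FLAG libraries alone can contribute. The measured covariances were 4.14 for hnRNP H1 with F, 2.8 with K and 2.98 with La/SSB, and the correlation of log2 fold changes across genes was 0.89 for hnRNP H1 with F and 0.64 with K; genes are not independent replicates. Part of the excess may still come from the shared FLAG libraries, since 3 controls do not split into separate sets of at least 2. Leaving out 1 FLAG library moved the overlap of La/SSB with hnRNP H1 between 812 and 1504, with F between 703 and 1328 and with K between 722 and 1352, and the genes higher in all 4 between 477 and 948, the highest each time without FLAG RIP 2.

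The direct test among the 4 specific RIPs, which leaves the FLAG libraries out of the contrast, asked where the 4 proteins' RNA differed. Sod3, the extracellular superoxide dismutase, on chromosome 14, had the lowest p (adjusted p = 2.47e-09), with 6643 ± 1953 CPM with hnRNP K against 203 ± 43.8 with hnRNP H1, 314 ± 77.3 with hnRNP F and 403 ± 43.2 with La/SSB. Bgn stood likewise at 14135 ± 4250 CPM with hnRNP K and 940 ± 196 with hnRNP H1 (log2 fold change -3.91 ± 0.30, hnRNP H1 against K). Zc3h13, a component of the complex that methylates mRNA, showed the opposite, with 8475 ± 1896 CPM with hnRNP H1, 15806 ± 7117 with hnRNP F, 151 ± 31.2 with hnRNP K and 406 ± 99.9 with La/SSB. Prpf19, a splicing factor, had 2257 ± 305 and 3447 ± 1345 CPM with hnRNP H1 and F against 95.8 ± 14.8 and 135 ± 42.1 CPM with hnRNP K and La/SSB, and Ccdc47, of the endoplasmic reticulum, was higher with hnRNP H1 than with K by 5.56 ± 0.34. In all 4422 transcripts differed (5819 at an unadjusted p under 0.05). Of the fixed genes Gap43 differed (adjusted p = 0.0157), with hnRNP F above K by 1.36 ± 0.40. Ssb differed (0.00042), with a log2 fold change of -2.52 ± 0.41 for hnRNP K against La/SSB. So did Actb (0.00292) and Hnrnph1 (0.0253), while Nrn1 (0.228) and Hnrnpf (0.331) did not pass.

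In the 5 pairs tested after the data were seen, hnRNP and SR protein genes were higher with hnRNP H1 than with K at a median of 2.49 (28 higher and 6 lower of 47; adjusted p = 5.23e-09, and adjusted p = 0.00944 with an estimated correlation), and with hnRNP F than with K at 2.43 (26 higher and 5 lower; adjusted p = 3.83e-09, and 0.0126 with an estimated correlation). Schwann cell transcripts were higher with hnRNP K than with La/SSB at a median of 0.96 (7 higher and 0 lower of 31; adjusted p = 6.77e-05, and 0.012 with an estimated correlation). The pair counts were 3767 transcripts for hnRNP H1 against K, 3826 for F against K, 2155 for H1 against La/SSB, 1663 for F against La/SSB and 1674 for K against La/SSB.

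hnRNP H1 against hnRNP F asked whether these paralogs held different RNA. No transcript passed with edgeR (0 called, 1339 at an unadjusted p under 0.05); DESeq2 called 81. edgeR called 4 when scaled by total counts, 9 with all 18 libraries in the fit and 1 with only the 6 libraries. Among the lowest p values were LOC100363452 (log2 fold change -2.21 ± 0.36, adjusted p = 0.0943), Kpna6, an importin alpha (2.55 ± 0.47, adjusted p = 0.102), and Lyve1, a hyaluronan receptor (-1.74 ± 0.33, adjusted p = 0.102). Gap43 had -0.30 ± 0.39 (adjusted p = 0.848) and Nrn1 -0.62 ± 0.63 (adjusted p = 0.789). As a group, ribosomal proteins were lower with hnRNP H1 than with hnRNP F at a median of -1.09 (0 of 70 called, 27 lower adjusted over the list alone; adjusted p = 1.8e-22), and oxidative phosphorylation at -0.81 (0 of 69 called, 0 adjusted over the list alone; adjusted p = 1.38e-09), both with adjusted p = 0.41 with an estimated correlation. Macrophage and leukocyte transcripts were lower at -0.55 (adjusted p = 0.000933) and translation factors with 5 prime TOP mRNAs at -0.53 (adjusted p = 0.00213), again with adjusted p = 0.41 with an estimated correlation for both. Axonally localized mRNAs (-0.64, adjusted p = 0.0224) and chaperones (-0.42, 0.0224) were lower and La-bound small RNAs higher (0.20, 0.00513), all with adjusted p = 0.41 with an estimated correlation. Those of fibroblasts and perineurium were lower (-0.37, adjusted p = 0.0313, and 0.593 with an estimated correlation). These 4 calls hung on single libraries: without hnRNP F RIP 2 the adjusted p was 0.327, 0.085 and 0.206 for the first 3, and without hnRNP F RIP 1 it was 0.158 for the fibroblast list. hnRNP and SR protein genes stood at 0.02 (adjusted p = 0.973). Simulated data with as many libraries returned 45.5% of 8-fold, 16.4% of 4-fold and 3% of 2-fold differences here, so most 2-fold differences were not detectable.

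The FLAG RIP against Input asked how the control precipitate differed from the starting RNA. Jun, the injury-induced transcription factor, was at 1132 ± 328 CPM in the FLAG RIP and 297 ± 66.7 CPM in Input (log2 fold change 1.93 ± 0.26, adjusted p = 0.000176). Itga6, the laminin receptor subunit of Schwann cells, fell to 86.6 ± 19.4 from 407 ± 82.2 CPM (-2.23 ± 0.28, adjusted p = 8.41e-05), and RNaseP_nuc, the RNA of the tRNA-processing ribonuclease, on chromosome 15, fell to 11.6 ± 8.17 from 362 ± 110 CPM (-4.97 ± 0.65, adjusted p = 0.000125). Schwann cell transcripts fell in 9 of 31 and rose in 2 (the same adjusted over the list alone; median -0.74, adjusted p = 0.000745), which held with an estimated correlation (adjusted p = 0.0182). So did the fall of La-bound small RNAs in 16 of 54 entries (23 adjusted over the list alone). Their median was -2.27, or -2.21 with entries at 0 reads set to their bounds (adjusted p = 1.66e-09, and 0.0441 with an estimated correlation). Oxidative phosphorylation rose in 17 of 69 with 0 lower (22 adjusted over the list alone; median 1.15, adjusted p = 8.88e-09, but adjusted p = 0.284 with an estimated correlation). Ribosomal proteins fell in 6 of 70 (2 adjusted over the list alone; median -0.59, adjusted p = 0.000722, but adjusted p = 0.761 with an estimated correlation). Fibroblast and perineurial transcripts (median -0.46, adjusted p = 0.00917, and 0.655 with an estimated correlation) lost their call without Input 1 (0.101) or FLAG RIP 2 (0.276). hnRNP and SR protein genes (0.77, adjusted p = 0.0337, and 0.284 with an estimated correlation) lost theirs without Input 1 (0.0553) or FLAG RIP 1 (0.0755), and with the length trend removed (0.0962). Ssb was higher in the FLAG RIP (1.63 ± 0.37, adjusted p = 0.00744) and Gap43 lower (-1.85 ± 0.41, adjusted p = 0.00614). Nrn1 was lower as well, near the threshold (-1.89 ± 0.64, adjusted p = 0.0473). Of genes named above as lower than FLAG in a specific RIP, Pfn1, Cfl1, Atp5b, Uqcrc1, Srsf5, Hnrnpa2b1 and Jun were higher in the FLAG RIP than in Input. Rplp0 was lower there (-0.93 ± 0.29). Gains in the FLAG RIP, as of oxidative phosphorylation, add to falls against FLAG in the specific RIPs. In all 2150 transcripts were called, 1159 higher and 991 lower, against 633 and 1023 when scaled by total counts, and 596 and 980 with 1 subtracted from every count. Both moved the median of all transcripts from 0.30 to 0.11. The count was 1011, 1101 and 1239 without Input 1, 2 and 3, 3618 without FLAG RIP 2 and 414 with FLAG RIP 2 alone. With only the 6 libraries it was 32, under which Jun (adjusted p = 0.0597), Ssb (0.116) and Gap43 (0.11) no longer passed, while Itga6 and RNaseP_nuc did.

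hnRNP H1 RIP against Input asked which RNAs were enriched over the starting axoplasm. Dpysl2 rose to 2366 ± 159 from 262 ± 34.4 CPM (log2 fold change 3.18 ± 0.25, adjusted p = 1.11e-07), Kpnb1 to 3801 ± 172 from 479 ± 17.7 CPM (2.99 ± 0.32) and Jun to 1945 ± 171 from 297 ± 66.7 CPM (2.71 ± 0.27). hnRNP and SR protein genes rose in 17 of 47 and fell in 4 (19 and 4 adjusted over the list alone; median 1.31, adjusted p = 6.06e-06, but adjusted p = 0.0533 with an estimated correlation), with Hnrnpul2 at 3.16 ± 0.32. Itgb3, the platelet integrin chain, had one of the largest rises (5.15 ± 0.66). Ribosomal proteins fell in 55 of 70 with 0 higher (58 adjusted over the list alone; median -2.82, adjusted p = 3.95e-38, but adjusted p = 0.158 with an estimated correlation), as Rps4x did to 188 ± 46.6 from 1958 ± 101 CPM. Translation factors with 5 prime TOP mRNAs fell in 17 of 31 and rose in 4 (20 and 6 adjusted over the list alone; median -1.78, adjusted p = 6.06e-06, but adjusted p = 0.262 with an estimated correlation). Oxidative phosphorylation fell in 34 of 69 with 0 higher (40 adjusted over the list alone; median -1.52, adjusted p = 7.6e-12, but 0.262 with an estimated correlation). Fibroblast and perineurial transcripts fell in 10 of 28 with 3 higher (13 and 3 adjusted over the list alone; median -0.70, adjusted p = 8.75e-05, but 0.262 with an estimated correlation). La-bound small RNAs rose in 13 of 54 (14 adjusted over the list alone; median 1.73, adjusted p = 0.00331, but 0.262 with an estimated correlation). Macrophage and leukocyte transcripts fell in 11 of 27 with 1 higher (13 and 1 adjusted over the list alone; median -1.28, adjusted p = 0.000382, but 0.262 with an estimated correlation). Erythrocyte transcripts (median -1.38, adjusted p = 0.0101, and 0.262 with an estimated correlation) and axonally localized mRNAs (-0.52, 0.0357, and 0.349 with an estimated correlation) lost their calls with the length trend removed (both 0.0753), the second also without hnRNP H1 RIP 1 (0.0779). Gap43 had 1.09 ± 0.40 (adjusted p = 0.0523) and Nrn1 -0.03 ± 0.62 (adjusted p = 0.981). In all 3207 transcripts were called, 1783 higher and 1424 lower, against 1177 and 2615 when scaled by total counts, with the median of all transcripts at -0.56 in place of -0.02.

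With hnRNP F against Input the same question gave Nefm at 356 ± 222 against 29.9 ± 20.6 CPM (log2 fold change 3.57 ± 0.64, adjusted p = 0.000415) and Itgb3 at 5.83 ± 0.68. hnRNP and SR protein genes rose in 19 of 47 and fell in 3 (20 and 3 adjusted over the list alone; median 1.27, adjusted p = 1.12e-06), which held with an estimated correlation (adjusted p = 0.0349). Ribosomal proteins fell in 40 of 70 with 0 higher (45 adjusted over the list alone; median -1.70, adjusted p = 2.05e-20, but adjusted p = 0.432 with an estimated correlation), with Rplp0 at 399 ± 101 against 2784 ± 351 CPM. Oxidative phosphorylation fell in 14 of 69 and rose in 1 (the same adjusted over the list alone; median -0.77, adjusted p = 4.64e-05, but adjusted p = 0.445 with an estimated correlation). Translation factors with 5 prime TOP mRNAs fell in 12 of 31 and rose in 5 (18 and 7 adjusted over the list alone; median -1.19, adjusted p = 0.00102, but 0.445 with an estimated correlation). Transcripts of fibroblasts and perineurium fell in 7 of 28 and rose in 1 (9 and 2 adjusted over the list alone; median -0.75, adjusted p = 0.00192, but 0.445 with an estimated correlation). The elongation factor Eef1a1 fell by 2.56 ± 0.27 and Dcn by 2.36 ± 0.27. In all 2514 transcripts were called, 1554 higher and 960 lower, against 967 and 1934 when scaled by total counts, with the median of all transcripts at -0.49 in place of 0.05. Without hnRNP F RIP 3 the count was 1675.

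hnRNP K RIP against Input asked the same of hnRNP K. Sod3 rose to 6760 ± 1844 from 847 ± 278 CPM (log2 fold change 3.00 ± 0.30, adjusted p = 9.57e-06), Col6a3, a collagen VI chain, to 1615 ± 325 from 342 ± 74.1 CPM (2.24 ± 0.27) and Sox10, the transcription factor of the Schwann cell lineage, to 524 ± 138 from 105 ± 24.8 CPM (2.32 ± 0.37, adjusted p = 0.000272). Schwann cell transcripts rose in 6 of 31 and fell in 1 (9 and 1 adjusted over the list alone; median 0.81, adjusted p = 0.000944), which held with an estimated correlation (adjusted p = 0.0254). Ribosomal proteins fell in 50 of 70 and rose in 1 (58 and 1 adjusted over the list alone; median -2.29, adjusted p = 1.96e-39, but adjusted p = 0.0853 with an estimated correlation). Oxidative phosphorylation fell in 29 of 69 with 1 higher (50 and 1 adjusted over the list alone; median -1.72, adjusted p = 2.63e-15, but 0.0853 with an estimated correlation). hnRNP and SR protein genes fell in 13 of 47 and rose in 2 (21 and 5 adjusted over the list alone; median -0.99, adjusted p = 0.000356, but 0.0775 with an estimated correlation). Hnrnpa1 fell to 29.8 ± 6.49 from 143 ± 36.9 CPM. Chaperones fell in 7 of 25 and rose in 1 (13 and 1 adjusted over the list alone; median -1.31, adjusted p = 0.0002, but 0.0853 with an estimated correlation). Translation factors with 5 prime TOP mRNAs fell in 13 of 31 and rose in 3 (19 and 4 adjusted over the list alone; median -1.42, adjusted p = 6.59e-08, but 0.0974 with an estimated correlation). Fibroblast and perineurial transcripts had a median of 0.17 (adjusted p = 0.0146, and 0.571 with an estimated correlation). They lost the call without Input 3 (0.0897), with the length trend removed (0.0827) and when scaled by total counts (-0.49, 0.198). Tpt1, a TOP mRNA, fell to 162 ± 30.2 from 1976 ± 81.5 CPM and RNaseP_nuc by 6.55 ± 0.71. In all 1736 transcripts were called, 875 higher and 861 lower, against 306 and 2173 when scaled by total counts, with the median of all transcripts at -0.77 in place of -0.10. The count was 4169 with only the 6 libraries; it was 811, 1154 and 1090 without hnRNP K RIP 1, 2 and 3, and 1049 and 1012 without Input 2 and 3.

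La/SSB RIP against Input gave 5 calls, 3 higher and 2 lower (1059 at an unadjusted p under 0.05; DESeq2 called 77, and edgeR 102 with only the 6 libraries and 9 with the length trend removed). RNase_MRP, the RNA of a ribonuclease that processes ribosomal RNA, had 243 ± 59.9 against 18.6 ± 2.44 CPM (log2 fold change 3.70 ± 0.67, adjusted p = 0.0478). Epb41l2 had 120 ± 30.7 against 7.14 ± 7.03 CPM (4.07 ± 0.59, adjusted p = 0.0109) and LOC100363112 3.55 ± 0.56 (adjusted p = 0.0177). AABR07054189.1 had -1.63 ± 0.27 (adjusted p = 0.0177). Without Input 2 or La/SSB RIP 3 there were 2 calls, and without any 1 of the other 4 libraries 0. As a group, La-bound small RNAs rose against Input at a median of 1.96 (0 of 54 called, 14 higher adjusted over the list alone; adjusted p = 1.94e-12, but adjusted p = 0.0605 with an estimated correlation). The 7SK entry of lowest p had 3.81 ± 0.73 (adjusted p = 0.0635). Ribosomal proteins stood at -0.63 (1 lower of 70, 6 adjusted over the list alone; adjusted p = 6.68e-14, but adjusted p = 0.413 with an estimated correlation). Fibroblast and perineurial transcripts (median -0.29, adjusted p = 0.000911), oxidative phosphorylation (-0.39, 0.00377), axonally localized mRNAs (-0.32, 0.00663) and hnRNP and SR protein genes (-0.09, 0.0457) were called lower. With an estimated correlation their adjusted p was 0.413, 0.53, 0.413 and 0.413. Without La/SSB RIP 1 the last 3 had adjusted p = 0.786, 0.113 and 0.094, and without Input 1 the first had 0.0764. hnRNP and SR protein genes turned to 0.09 (adjusted p = 0.0858) when scaled by total counts. Ssb had 1.59 ± 0.37 (adjusted p = 0.164), Gap43 0.08 ± 0.40 (adjusted p = 0.986) and Nrn1 -0.66 ± 0.62 (adjusted p = 0.898). With as many libraries, 47% of 8-fold and 0% of 2-fold differences were returned in simulated data. The split was 5 higher and 1 lower when scaled by total counts and 2 and 3 with RLE. Total counts moved the median of all transcripts to 0.20.

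**Figure D4:**
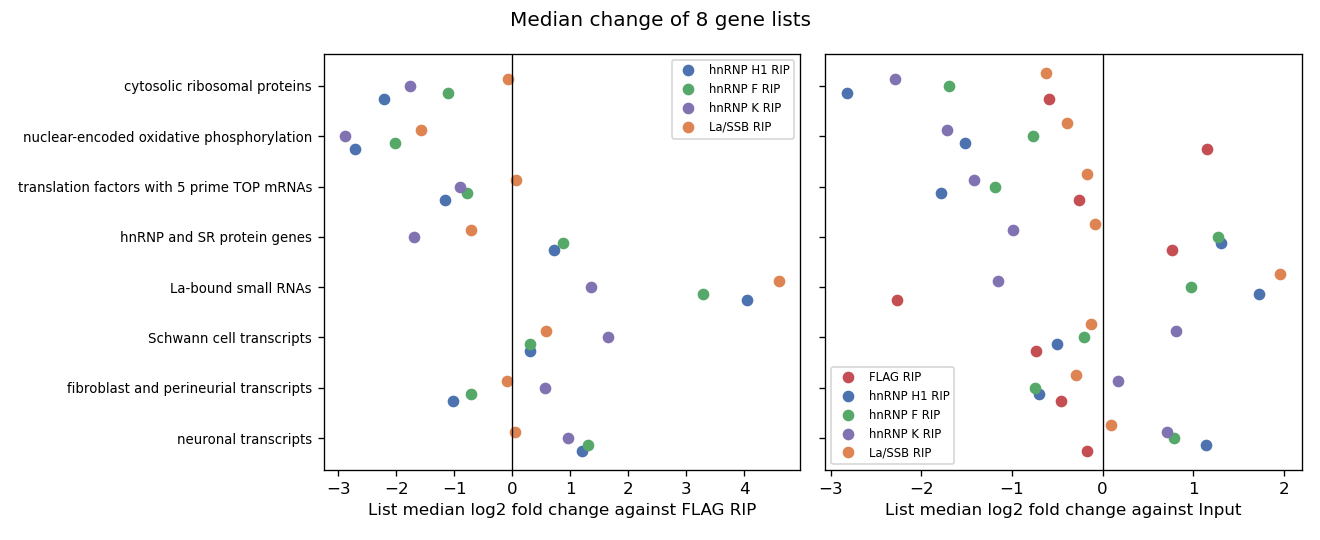
Median log2 fold change of 8 gene lists against FLAG RIP in the 4 specific RIPs and against Input in all 5 RIPs. The FLAG RIP itself stood higher than Input in oxidative phosphorylation, which adds to the falls of that list against FLAG. Oxidative phosphorylation is at -2.71 with hnRNP H1 and -2.88 with hnRNP K against FLAG, while La-bound small RNAs are at 4.05 and 4.59 with hnRNP H1 and La/SSB; with total counts the fibroblast median with hnRNP K against Input turns from 0.17 to -0.49 and the hnRNP and SR median with La/SSB against Input from -0.09 to 0.09.

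Called against both references, in a count added after the data were seen, 1245 genes were higher with hnRNP H1 than in FLAG RIP and than in Input (326 if the calls were independent), which is 51.4% of those higher than FLAG. The numbers were 1074 for hnRNP F (258 if independent; 48.8%), 555 for hnRNP K (127; 28.9%) and 3 for La/SSB (0.2%). The RIP libraries are the same in both comparisons, which alone ties them together. Simulated without differences, 0 genes were higher than both, with a covariance of 0.32 to 0.33 and a correlation of 0.49 to 0.5 across genes. This simulation also gave every group the same mean and spread per gene, so few calls could arise in it. The measured covariances were 2.46, 2.03, 1.44 and 0.67 for hnRNP H1, F, K and La/SSB, and the correlations 0.71, 0.66, 0.6 and 0.43, so that of La/SSB lay below its simulated value of 0.49. Itgb3 and Muc6, a mucin, were among the largest with hnRNP H1 (6.72 ± 0.74 and 5.19 ± 0.86 against FLAG, 5.15 ± 0.66 and 5.34 ± 0.83 against Input), and Sod3 and Tet3, a DNA demethylase, with hnRNP K (4.07 ± 0.32 and 4.37 ± 0.32 against FLAG, 3.00 ± 0.30 and 2.57 ± 0.28 against Input). The 3 with La/SSB were Epb41l2, LOC100363112 and RNase_MRP. Lower than both were 1100 genes with hnRNP H1, 633 with hnRNP F, 700 with hnRNP K and 1 with La/SSB. The deposited fold changes of the authors correlated with those here at 1 across transcripts in each of the 9 pairs, and at most 3 calls per pair were not called in the same direction there. The authors' FDR values called more of the tested transcripts in every pair. The counts were 6120 against 5245 here for hnRNP H1 and 3645 against 2492 for La/SSB against FLAG, and 48 against 5 for La/SSB against Input.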

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

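The tests of FLAG levels against Input, the direct contrasts of hnRNP H1 or F with hnRNP K or La/SSB and of hnRNP K with La/SSB, the fit with FLAG RIP 2 alone, and the choice of genes without the library they are measured in were chosen only after the results they bear on were seen.

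In direct contrasts of 2 specific RIPs, 2 gene lists differed between antibodies with an estimated correlation as well. hnRNP and SR protein genes had a median log2 fold change of 2.49 for hnRNP H1 against K (adjusted p = 5.23e-09, and 0.00944 with an estimated correlation). For hnRNP F against K their median was 2.43 (3.83e-09, and 0.0126 with an estimated correlation). For hnRNP H1 against La/SSB it was 1.29 (15 higher and 2 lower of 47; 3.43e-09, and 0.0109 with an estimated correlation), and for hnRNP F against La/SSB 1.43 (18 higher and 2 lower; 4.45e-10, and 0.00799 with an estimated correlation). Schwann cell transcripts had a median of 0.96 for hnRNP K against La/SSB (6.77e-05, and 0.012 with an estimated correlation).

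The first pattern is the sets of genes higher in a specific RIP than in FLAG RIP, 2433 with hnRNP H1, 2204 with hnRNP F, 1921 with hnRNP K and 1208 with La/SSB. If these genes only had low levels in the FLAG RIP, their fold changes against Input should be near 0; the median against Input was 0.61 and 0.59 of that against FLAG for hnRNP H1 and F, and 0.64 to 0.66 and 0.59 to 0.64 in RIP libraries left out of the choice of genes, which argues against it as the whole cause. For La/SSB these shares were 0.19 and 0.18 to 0.26, near what low FLAG levels predict. For hnRNP K they were 0.41 and 0.41 to 0.48, in between, so low FLAG levels as the whole cause stay open for both. If the table was filtered on La/SSB RIP 1, entries low there are missing, which could also add to the 1208 genes. That was not tested. That FLAG RIP libraries 1 and 3 merely missed these transcripts stays open for all 4: with FLAG RIP 2 as the lone control the median kept 0.94, 0.93, 0.93 and 0.87 of its size, which met the bound set beforehand (0.8), but FLAG RIP 2 took part in choosing these genes, and for genes chosen without it the median against FLAG RIP 2 was only 0.69, 0.67, 0.62 and 0.52 of that against FLAG RIP 1 and 3. Binding to the precipitated protein, which the design names, was not tested apart from this. Genes lower than FLAG were not tested against Input in this way, so high levels in the FLAG RIP stay open for them.

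The second pattern is the lower level of ribosomal protein and oxidative phosphorylation transcripts in the hnRNP H1, F and K RIPs than in Input. Both lists hold short transcripts, and removing each library's trend over transcript length left as little as 0.65 of the median for each list, in hnRNP K both times, so the bound set beforehand (0.8 in all 3 RIPs) was missed and length may account for part of the difference. Length as the whole cause is argued against by what was left: ribosomal proteins stayed at -2.26 with hnRNP H1 and -1.35 with hnRNP F (adjusted p = 1.6e-30 and 2.67e-15; 2.93e-24 with hnRNP K) and oxidative phosphorylation at -1.18, -0.61 and -1.12 with hnRNP H1, F and K (2.79e-07, 0.00345 and 1.91e-07). Among 10000 random lists matched on length and abundance together, the ribosomal median lay at percentile 0 in all 3 RIPs and the oxidative phosphorylation median at percentile 0.39 or lower. Both lists thus lay lower than other transcripts of similar length and abundance. The random lists drew transcripts independently from bins, while members of a gene family can vary together. Length as the whole cause is therefore not excluded. A protein-bound RNA pool that holds less of these mRNAs remains a hypothesis, and neither list's call holds with an estimated correlation.

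The third pattern is the rise of La-bound small RNAs, not only with La/SSB but with all 4 antibodies, over FLAG RIP. Their median exceeded that of 343 other transcripts of 77 to 347 nt by at least 0.73 of its size. For those others it was 1.08, 0.84, 0.22 and 0.90 for hnRNP H1, F, K and La/SSB. Lying in that length range thus did not by itself go with as large a rise. Small nucleolar and Cajal body RNAs, a class outside the list given below, rose alike, at 4.06, 3.46, 1.60 and 4.17. The 343 others were not matched to the list's median length of 107 nt, so short length as the cause stays open. Low levels in the FLAG RIP stay open for hnRNP H1, F and La/SSB, where the median against Input was at least 0.30 of that against FLAG. For hnRNP K the share was -0.85, with a median of -1.16 against Input, which is what low FLAG levels predict. Binding by La/SSB, which the design names, was not tested apart from this. If the table was filtered on La/SSB RIP 1, entries low there are missing, which could by itself raise the La/SSB median. That was not tested either.

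Other splits of the same libraries were counted for each comparison. Each pair of groups has 10 splits, the real one included, which are too few for a share under 0.05. The real split called 5245 genes for hnRNP H1 against FLAG (highest other 0), 4473 for hnRNP F (1), 4497 for hnRNP K (0) and 2492 for La/SSB (1). It called 2150 for FLAG RIP against Input (0), 3207 for hnRNP H1 (0), 2514 for hnRNP F (0), 1736 for hnRNP K (0) and 5 for La/SSB (0). In each of these 1 split of 10, the real one, gave as many. For hnRNP H1 against F all 10 splits gave as many as the real 0 calls of edgeR (1339 at an unadjusted p under 0.05; 81 with DESeq2). Among the 4 specific RIPs 1 of 100 drawn splits, the real one, gave 4422 genes (highest other 1754). Chance is therefore unlikely there, but a draw of 100 splits cannot exclude it.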

How the results depend on the processing

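The settings chosen only after the data were seen were FLAG RIP 2 alone, 1 subtracted from every count, the length trend removed, counts summed per symbol, the overlaps without 1 library and the choice of genes without the library they are measured in. Of 832 values of named genes, 829 kept direction and side of the threshold with RLE, 829 with robust moderation, 831 with no filter and 778 with total counts, as did 811 of 817 with a filter of 30 reads in 3 libraries. With DESeq2 773 of 826 did, and over all fits without 1 library 4691 of 4992, with 277 no longer called and 2 reversed. With only the 6 libraries 673 of 802 did, and with FLAG RIP 2 alone 310 of 427, with 111 no longer called and 6 reversed. Counts moved over 1.5 times as follows, and the cause was not tested. With FLAG RIP 2 alone, which is then assumed to vary like the other groups, 3372, 2578, 2672 and 349 genes were called for hnRNP H1, F, K and La/SSB against FLAG, and 414 for FLAG RIP against Input. Muscle transcripts called lower with all 3 FLAG libraries turned there: Ckm 0.17, Tnnc2 1.01 and Myh1 0.12 with hnRNP H1, Mylpf 1.05 and Mb 0.90 with hnRNP F, and Myl1 0.47 with hnRNP K. None of these rises was called. With only the 6 libraries compared the counts were 2891, 1640, 2751 and 674 against FLAG in the same order, 1 for hnRNP H1 against F, 32 for FLAG RIP against Input, 4169 for hnRNP K and 102 for La/SSB against Input. In these fits the spread came from the compared groups alone, with fewer libraries to estimate it. Counts fell in every comparison with the FLAG RIP, whose median SD was highest (0.98). They rose for hnRNP K (0.38) and La/SSB (0.51) against Input (0.47). The main counts thus depend on the spread shared over groups. For hnRNP H1 against F, total counts gave 4 genes, all 18 libraries 9 and DESeq2 81. For La/SSB against Input, DESeq2 gave 77, removal of the length trend 9 and counts summed per symbol 2. With total counts the overlap of genes higher than FLAG was 661 between hnRNP H1 and K and 599 between hnRNP F and K.

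Replicate numbers are shared between groups, but the labels do not say that they pair the libraries. Libraries of the same number had deviations correlated at 0.01 to 0.19 (mean 0.08, other numbers -0.04), over 0.1 in 11 of 45 pairs, and 18 of 18 libraries correlated best with their own number, a hint from the data and not the design. The share of skeletal muscle transcripts was also highest in number 1 and lowest in number 2 in every group, as in Input (0.231%, 0.028% and 0.112%). Libraries of 1 number may thus share starting material, which the main tests leave out. With the replicate number as a block 9 genes were called for hnRNP H1 against F and 33 for La/SSB against Input. Lists called with the block were 8 for hnRNP F and 7 for La/SSB against FLAG, and 8 for hnRNP F against Input. No other count of genes or lists moved over 1.5 times with the block.

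Gene lists called with an estimated correlation numbered 0 for hnRNP H1, 0 for hnRNP F, 1 for hnRNP K and 1 for La/SSB against FLAG, and 0 for hnRNP H1 against F. Against Input they numbered 2 for FLAG RIP, 0 for hnRNP H1, 1 for hnRNP F, 1 for hnRNP K and 0 for La/SSB. With total counts 9 lists were called for hnRNP F against Input.

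Without 1 library in turn, counts of called genes ran from 4184 to 5935 for hnRNP H1, 3437 to 5125 for hnRNP F, 2902 (without hnRNP K RIP 1) to 5204 for hnRNP K and 1239 (without La/SSB RIP 1) to 3898 (without FLAG RIP 2) for La/SSB against FLAG; for La/SSB the count was 1583 without La/SSB RIP 3. They ran from 1011 (without Input 1) to 3618 (without FLAG RIP 2) for FLAG RIP against Input, with 1101 and 1239 without Input 2 and 3. Against Input they ran from 2348 to 2627 for hnRNP H1, 1675 (without hnRNP F RIP 3) to 2420 for hnRNP F, 811 (without hnRNP K RIP 1) to 1183 for hnRNP K and 0 to 2 for La/SSB. For hnRNP K against Input they were 1154 and 1090 without hnRNP K RIP 2 and 3, and 1049 and 1012 without Input 2 and 3. Among the 4 RIPs they ran from 3385 to 4394, and hnRNP H1 against F stayed at 0. Called lists ran from 3 to 7 for La/SSB against FLAG (7 without FLAG RIP 1 or La/SSB RIP 3), 5 (without hnRNP F RIP 2) to 8 for hnRNP H1 against F and 5 to 9 for hnRNP F against Input (9 without Input 2 or hnRNP F RIP 1). Overlaps ran from 812 to 1504 for hnRNP H1 with La/SSB, 703 to 1328 for hnRNP F, 722 to 1352 for hnRNP K and 477 to 948 for all 4, each highest without FLAG RIP 2. Without FLAG RIP 1, Mb in hnRNP F RIP against FLAG RIP turned to 1.43 (otherwise -6.29 to -5.44) and Myl1 in hnRNP K RIP against FLAG RIP to 0.79 (otherwise -5.90 to -5.12). Depth limits what low counts show: 3 reads stand for 0.651 CPM in the shallowest library.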

Other observations

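The gene classes below were chosen and tested only after the data were seen.

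Small nucleolar and Cajal body RNAs, which guide the chemical modification of other RNAs in the nucleus, stood higher than FLAG with each antibody. Of 66 entries 46 rose with hnRNP H1 and 0 fell (median log2 fold change 4.06, adjusted p = 2.03e-10, and 0.00445 with an estimated correlation). With La/SSB 47 rose and 0 fell (4.17, adjusted p = 1.45e-20, and 0.000423 with an estimated correlation). A filter of the table on La/SSB RIP 1 could have added to this rise too. With hnRNP F 42 rose (3.46), and with hnRNP K 19 rose and 3 fell (1.60, adjusted p = 0.00063, but 0.0694 with an estimated correlation). SNORA21 had 627 times its pooled FLAG rate with hnRNP H1 (counting interval 214 to 3047) and 115 times with La/SSB (38.9 to 559). Against Input the same class fell in the FLAG RIP in 27 of 70 entries (median -2.38, adjusted p = 1.35e-10, and 0.0024 with an estimated correlation), and with La/SSB its median was 1.41 with 0 entries called by edgeR (adjusted p = 6.54e-11, and 0.00302 with an estimated correlation). With hnRNP H1 it was 1.21 against Input (14 rose of 70; adjusted p = 0.00833, but 0.217 with an estimated correlation). With hnRNP F it was 0.66 (adjusted p = 0.414) and with hnRNP K -0.84 (adjusted p = 0.095), neither called.

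Collagen genes, which code for the fibrous matrix of the nerve sheaths, rose with hnRNP K against FLAG in 19 of 37 and fell in 2 (median 1.90, adjusted p = 3.25e-09, but 0.0518 with an estimated correlation). They also rose against FLAG with hnRNP H1 (14 rose and 3 fell; 1.07, adjusted p = 0.00975, but 0.323 with an estimated correlation), hnRNP F (16 and 2; 1.14, adjusted p = 0.000288, but 0.152 with an estimated correlation) and La/SSB (10 and 0; 0.87, adjusted p = 5.21e-05, but 0.113 with an estimated correlation). Against Input 10 rose with hnRNP K and 0 fell (0.49, adjusted p = 0.001, but 0.278 with an estimated correlation), and in the FLAG RIP 14 fell and 0 rose (-0.83, adjusted p = 9.67e-08, and 0.0379 with an estimated correlation). The class was not called against Input with hnRNP H1 (3 rose and 7 fell, adjusted p = 0.424), hnRNP F (4 and 6, adjusted p = 0.938) or La/SSB (0 and 0, median -0.10, adjusted p = 0.133). Across transcripts, which are not independent replicates, log2 fold change correlated with transcript length at 0.25 for hnRNP K against Input and 0.20 for hnRNP K against FLAG.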
